A study of Mus musculus with 24 samples.

How the data were processed

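RNA sequencing was carried out on cells sorted from the livers of female C57BL/6 mice that had eaten a methionine- and choline-deficient diet for 2 weeks, a dietary model of steatohepatitis. The mice had received liposomes carrying the membrane dye DiI, either empty or loaded with curcumin, a plant polyphenol, by intravenous injection 24 hours earlier. Cells positive for CD11c and MHC class II were sorted as DiI-positive (dye taken up) or DiI-negative. Per the labels' protocols, RNA from the sorted cells was amplified as cDNA with a low-input SMARTer kit and made into libraries with Nextera XT. The labels hold 24 sample records for 12 library codes, 2 records to a code, and the deposited columns carry the 12 codes, so each code was counted as 1 library. The codes were read against the series design text: EL and CL as empty and curcumin liposome, P and N as DiI-positive and DiI-negative. This gave 4 groups of 3 libraries. The sources used here do not say whether the 3 libraries of a group came from separate mice or from pools, so p-values measure the spread between these libraries, which may be partly technical.

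The deposited values are gene-level log2 values, 1 column per library, made by the authors. Per the submitters' processing notes, STAR 2.4.0d, DESeq2 1.8.1 and the GRCm38 genome build were used. The read counter, the annotation and the transform are not given in the sources used here. The values have the form of a shrunken log2 scale (a regularized log). They lie between -3.62 and 19.4, 20918 of 45792 genes are listed at 0 in all 12 libraries, and the spread between libraries narrows towards 0 for genes with low values. A fold change from such values understates the change of low genes, and all fold changes below are on this scale. Between libraries the values correlated with r from 0.9735 to 0.9942 over the genes tested. The number of reads per library is not given in the values. A relative depth index was derived from 1009 genes whose values show a single count in 1 library; it varied 1.65-fold between the deepest and the shallowest library and gives an order, not a read number. Precision is therefore given as the spread between libraries only.

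The design fixed before the data were examined assumed raw counts and named an edgeR test, which was not run because the files hold log2 values. In its place limma 3.58.1 in R 4.3.3 was used with the same groups and contrasts. Genes with a mean log2 value of at least 4 over the 12 libraries were kept, which left 14227 of the 24874 genes not at 0 in all libraries. All 12 libraries entered 1 fit with a mean for each group and a shared spread (8 residual and 3.51 prior degrees of freedom). The prior variance followed the mean (eBayes with trend), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The contrasts were curcumin against empty liposome in each gate, DiI-positive against DiI-negative cells under each liposome, and the difference between the curcumin effects of the 2 gates. Adjusted p-values of genes below come from this limma fit unless another tool is named. Gene symbols, coordinates and gene types came from the GENCODE M21 annotation of GRCm38, and 99.2% of the genes not at 0 had a symbol.

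A fixed set of 31 gene lists (cell type markers and pathways) was tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Some lists share genes, so their calls are not independent. Marco, Vsig4, Cd163, Axl and Timd4 are in both the Kupffer cell and the scavenger receptor list. Apoe is in both the LXR target and the lipid-associated macrophage list, and Nr1h3 is in both the LXR target and the Kupffer cell list. Adjusted p-values of lists are Benjamini-Hochberg values over the 31 lists, and a list is said to have moved by camera at the preset correlation unless stated otherwise. Genes were named by a rule fixed before the data were examined. For each comparison it took the 10 largest rises and the 10 largest falls among genes past the threshold whose libraries did not overlap between the groups, with a mean log2 CPM of at least 4 and an official symbol (no immunoglobulin or T cell receptor segments, pseudogenes, mitochondrial or numbered clone genes). It took the 5 genes with the smallest p where fewer than 5 passed, and Itgax, H2-Ab1, Cd74, Tnf, Il1b, Il6, Il12b, Il10, Nfkbia and Hmox1 in every comparison. Of each list described it took up to 4 members with the smallest p. Genes outside the rule are said to have been chosen after their values were seen.

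The fit was tested on simulated log2 values for the 14227 genes, in which 200 genes were changed in each of 5 draws and each gate kept its own spread. A change of 1 on the log2 scale was recovered for 78.2% of genes in the curcumin comparison of DiI-positive cells, 69.3% in that of DiI-negative cells, and 74.6% and 73.1% in the comparisons of gates under empty and curcumin liposome. For a change of 0.5 the shares were 26.0%, 20.3%, 24.8% and 26.6%. Of the simulated calls, 29.9%, 5.28%, 7.08% and 8.65% were false in these comparisons. DiI-positive libraries varied more than DiI-negative libraries (median within-group SD 0.216 against 0.161), whereas the fit shares 1 spread. In this simulation, calls in the curcumin comparison of DiI-positive cells were less certain than their adjusted p, and real calls may be too. With a separate weight for each gate the first share was 19.2%, and that of DiI-negative cells rose to 14.4%. The gate difference in spread therefore does not account for all of the false calls. The simulation took each gene's spread from the few libraries of each gate and drew genes independently, and the shares depend on that setting.

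The alternatives planned beforehand were no filter, a stricter filter (at least 50 normalized units in at least 3 libraries), a fit of only the 6 libraries compared, the replicate number as a block, the block within liposome, and leaving out each library in turn. DESeq2 as an alternative test, size factors of another kind and voom quality weights need counts and were not run. Alternatives added after seeing the data were no variance trend, a robust prior, library weights, gate weights, quantile normalization, the depth index as a covariate, the mean values of 3 cell marker lists as covariates, and leaving out curcumin replicate 3 of both gates. The cell marker covariates were run only for the curcumin comparisons and the difference between gates. Figures were drawn with matplotlib 3.10.9.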

Results

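Gene expression was measured by low-input RNA sequencing in hepatic CD11c+ MHC class II+ cells of mice with diet-induced steatohepatitis, 24 hours after injection of DiI-labelled liposomes. There were 4 groups of 3 libraries: DiI-positive and DiI-negative cells after empty liposomes, and DiI-positive and DiI-negative cells after curcumin liposomes. Values are log2 normalized values on a shrunken scale, given as mean ± SD with n = 3, and log2 fold changes are given with their standard errors. The first principal component held 34% of the variance and separated DiI-positive from DiI-negative libraries, with scores from -27.7 to -6.51 and from 16.3 to 21.6. The second held 13.8% and set curcumin DiI-positive replicates 1 and 3 apart from each other, at 28.5 and -26.2. The relative depth index was lowest in empty DiI-positive replicate 2 (0.736) and highest in empty DiI-negative replicate 1 (1.22), and empty DiI-positive replicate 1 ranked 3 of 12 (1.15). The genes of the sorting gate were at high levels in every group: Cd74, the class II invariant chain, had means from 19.19 to 19.30, and Itgax, which encodes CD11c, from 12.54 to 13.23. These levels do not show that the cells were dendritic cells alone. Over the 12 libraries the mean of the B cell marker list ran from 11.08 to 12.94. That of cDC1 markers ran from 9.40 to 11.23 and that of cDC2 markers from 9.67 to 10.29. Means of different genes do not give cell shares.

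The comparison of DiI-positive with DiI-negative cells asks how cells that had taken up liposomes differed from cells of the same gate that had not. The genes named here are those the naming rule admits, which leaves out immunoglobulin segments. Among them, genes known from Kupffer cells, the resident macrophages of the liver, were the most strongly raised in DiI-positive cells after empty liposomes. Clec4f, a Kupffer cell lectin (chromosome 6, 83644542 to 83656187), stood at 13.02 ± 1.3 (SD, n = 3) in DiI-positive and 8.51 ± 0.47 in DiI-negative libraries, a log2 fold change of 4.52 ± 0.57 (limma adjusted p = 0.0047). The scavenger receptor Marco (3.86 ± 0.76), the secreted macrophage protein Cd5l (3.11 ± 0.50) and the complement receptor Vsig4 (3.04 ± 0.50) rose. The ficolin Fcna (2.63 ± 0.62), the interleukin-18 antagonist Il18bp (2.53 ± 0.26) and the iron exporter Slc40a1 (2.19 ± 0.35) also rose. Mmp12 (1.90 ± 0.28), Clec1b (1.89 ± 0.29) and the adhesion molecule Vcam1 (1.87 ± 0.36) completed the 10 largest rises under that rule. Limma adjusted p-values of the 10 ranged from 0.0015 to 0.047. Of the immunoglobulin segments, Ighv11-2 (3.76 ± 0.26) and Igkv14-126 (2.39 ± 0.23) rose more than some of these 10 and are described further below. The largest falls were in Il2rb, the beta chain of the interleukin-2 and interleukin-15 receptors (-2.29 ± 0.30), and in Cd209a, a dendritic cell lectin (-2.14 ± 0.29; chromosome 8, 3743397 to 3748984). Ddr1, a collagen receptor, fell by 2.00, and F13a1, coagulation factor XIII A, by 1.68. The other 6 are known from natural killer (NK) and cytotoxic cells, though Cd7 is also in the list of cDC2 markers used below. They were Klrb1c (-1.81 ± 0.31), Klrd1 (-1.78 ± 0.24), Cd7 (-1.77 ± 0.28), Ctsw (-1.65 ± 0.24), Ncr1 (-1.65 ± 0.33) and Nkg7 (-1.63 ± 0.21; chromosome 7, 43437073 to 43438249), with adjusted p between 0.0047 and 0.026.

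**Figure D1:**
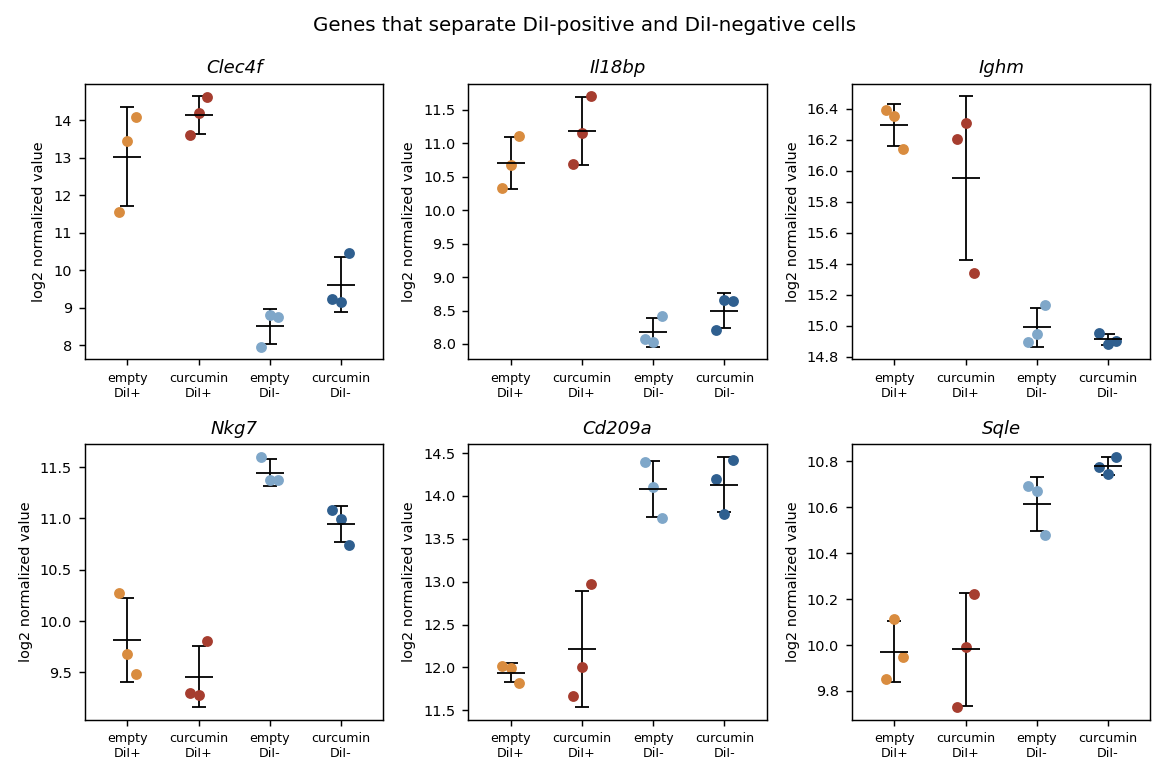
Log2 normalized values (y axis) of 6 genes in the 4 groups (x axis); dots are the 3 libraries of a group, and black bars are the mean and SD. In all 6 genes the 3 empty DiI-positive libraries lie apart from the 3 empty DiI-negative libraries, Clec4f, Il18bp and Ighm above them and Nkg7, Cd209a and Sqle below them.

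By gene list, 8 of 19 Kupffer cell markers rose after empty liposomes and none fell, with a list median of 1.17 (16 adjusted over the list alone). The call of this list was lost with an estimated correlation (adjusted p = 0.15). B cell markers rose in 8 of 14 genes with a median of 1.25 (14 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation). Among them were Fcrla (1.30 ± 0.20), the immunoglobulin heavy chain Ighm (1.30 ± 0.20), the transcription factor Ebf1 (1.16 ± 0.19) and Ms4a1, which encodes CD20 (1.30 ± 0.27). T and NK cell markers fell in 7 of 16 genes with a median of -0.78 (11 adjusted over the list alone), and this call held with an estimated correlation (adjusted p = 0.024). Its falls included Nkg7, Ccl5 (-1.46 ± 0.19), Klrb1c and Trbc2 (-0.79 ± 0.14), whereas the T cell receptor complex gene Cd3e, chosen after its value was seen, was at -0.21 (adjusted p = 0.70). Sterol biosynthesis genes fell in 3 of 20 (median -0.34; 4 adjusted over the list alone), and this call also held with an estimated correlation (adjusted p = 0.026). Sqle, squalene epoxidase, was at -0.64 ± 0.13 and Hmgcs1 at -0.72 ± 0.17. LXR target and lipid efflux genes moved the other way, with 4 of 13 raised (median 0.58; 7 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation). These were the desaturase Scd1 (1.45 ± 0.21), Apoc1 (1.43 ± 0.30), the cholesterol exporter Abca1 (1.01 ± 0.22) and the lipid transfer protein Pltp (0.91 ± 0.17). Proliferation genes fell in 5 of 20 (median -0.51; 7 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation), with Mki67 at -1.12 ± 0.23 and Stmn1 at -0.75 ± 0.14. Whether the changes of the sterol, LXR and proliferation lists reflect a different mix of cells was not tested. In the cDC2 list, 3 of 16 genes fell, Cd209a, Cd7 and the lectin Clec10a (-1.34 ± 0.24). Its median was -0.31 (4 fell and 2 rose adjusted over the list alone; adjusted p = 0.20 with an estimated correlation), and -0.15 without empty DiI-positive replicate 2 (adjusted p = 0.053). In the monocyte list Ly6c2 (-1.51 ± 0.27), the chemokine receptor Ccr2 (-0.58 ± 0.11) and F13a1 fell, 3 of 18 (8 adjusted over the list alone; adjusted p = 0.39 with an estimated correlation). Lipid-associated macrophage genes rose in 2 of 14, Mmp12 and Pld3 (median 0.34; 5 rose and 1 fell adjusted over the list alone), and scavenger receptor genes in 3 of 20, Vsig4, Marco and Mertk (median 0.42; 6 adjusted over the list alone). Vsig4 and Marco are also Kupffer cell markers. The calls of both lists were lost with an estimated correlation (adjusted p = 0.37 for each). The scavenger receptor median was 0.16 without empty DiI-positive replicate 3.

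The MHC class II presentation list was not called after empty liposomes (median 0.08, adjusted p = 0.56), although H2-Ob rose (0.96 ± 0.20) and H2-DMb1 fell (-0.41 ± 0.08). Nor was the list of mature, migratory dendritic cells (adjusted p = 0.87), in which the chemokine receptor Ccr7 rose (1.02 ± 0.20) and the chemokine Ccl22 fell (-1.22 ± 0.28). The NF-kB target list was also not called (median -0.11, adjusted p = 0.14); its member Il1a rose (1.38 ± 0.25), and Nfkb1 (-0.78 ± 0.11) and Bcl3 (-0.68 ± 0.16) fell. Lists of other cell types were called by camera: cDC1 markers (median -0.51), neutrophil markers (-0.58), hepatocyte markers (0.17) and sinusoidal endothelial markers (0.19). All 4 calls were lost with an estimated correlation (adjusted p from 0.47 to 0.57). Without empty DiI-positive replicate 3 the adjusted p was 0.24 for hepatocyte and 0.12 for sinusoidal endothelial markers. The only gene of these 4 lists past the threshold was the adhesion molecule Pecam1 (0.88 ± 0.13).

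In this comparison 419 of 14227 genes passed the threshold, 188 higher and 231 lower in DiI-positive cells, and 156 of them by more than 2-fold. The libraries of the groups did not overlap for 26.9% of genes, against the 10% that chance gives for 3 against 3. Of the cytokine and stress genes named in every comparison none passed; Hmox1, heme oxygenase 1, was at 0.75 ± 0.29 (adjusted p = 0.20) and Il1b at -0.24 ± 0.25 (adjusted p = 0.69). Without 1 library the count was 228, 144 and 263 when empty DiI-positive replicate 1, 2 or 3 was left out and 85, 108 and 147 when empty DiI-negative replicate 1, 2 or 3 was left out. It was 170 with the depth index as a covariate, 263 with no filter and 789 with library weights.

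After curcumin liposomes the same comparison was led by largely the same named genes. Clec4f was at 14.14 ± 0.50 (SD, n = 3) in DiI-positive and 9.62 ± 0.72 in DiI-negative libraries, a log2 fold change of 4.52 ± 0.57 (limma adjusted p = 0.0044). Marco (4.24 ± 0.76), Vsig4 (3.59 ± 0.50), Cd5l (3.51 ± 0.50), Fcna (3.30 ± 0.62), Slc40a1 (2.78 ± 0.35), Clec1b (2.72 ± 0.29), Il18bp (2.68 ± 0.26), Vcam1 (adjusted p = 0.0077) and the semaphorin Sema6d (2.28 ± 0.30) were the other rises. Cd209a (-1.92 ± 0.29), Cd7 (-1.87 ± 0.28), the NK receptor genes Klrk1 (-1.85 ± 0.37), Ncr1 (-1.63 ± 0.33) and Klrd1 (-1.54 ± 0.24), and Ddr1 (-1.74 ± 0.34) fell. So did Adgrg5 (-1.73 ± 0.37), Ccdc102a (-1.69 ± 0.33), F13a1 (-1.61 ± 0.33) and Uhrf1, a factor that maintains DNA methylation (-1.50 ± 0.32). Adjusted p-values of these 20 genes lay between 0.0021 and 0.028. Il6 fell by 0.46 (adjusted p = 0.027) at levels near the floor of the scale, 4.63 against 5.09.

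Of the lists, Kupffer cell markers rose in 12 of 19 genes (median 1.82; 16 adjusted over the list alone; adjusted p = 0.095 with an estimated correlation). B cell markers rose in 7 of 14 (median 1.11; 14 adjusted over the list alone; adjusted p = 0.18 with an estimated correlation), with Ebf1 at 1.03 ± 0.19 and Ighm at 1.04 ± 0.20. Lipid-associated macrophage genes, called under both liposomes, rose in 5 of 14 (median 0.58; 9 rose and 1 fell adjusted over the list alone; adjusted p = 0.18 with an estimated correlation). The last included Pld3 (1.32 ± 0.18), Mmp12 (1.74 ± 0.28), the cathepsin Ctsd (1.14 ± 0.22) and Apoe (1.46 ± 0.28). T and NK cell markers fell in 6 of 16 (median -0.91; 10 adjusted over the list alone) and sterol biosynthesis genes in 4 of 20 (median -0.36; 9 adjusted over the list alone). Both were also called with an estimated correlation (adjusted p = 0.024 in each). The 4 sterol genes were Sqle (-0.80 ± 0.13), Hmgcs1 (-0.98 ± 0.17), Mvd (-0.66 ± 0.11) and Cyp51 (-0.86 ± 0.18). LXR target genes rose in 6 of 13 and fell in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation), with Apoc1 at 1.93 ± 0.30 and Scd1 at 1.28 ± 0.21. Proliferation genes fell in 5 of 20 (median -0.79; 12 adjusted over the list alone; adjusted p = 0.064 with an estimated correlation), with Stmn1 at -0.86 ± 0.14 and Top2a at -1.48 ± 0.31. Scavenger receptor genes rose in 5 of 20 (median 0.69; 7 adjusted over the list alone; adjusted p = 0.18 with an estimated correlation), with the efferocytosis receptor Mertk at 1.64 ± 0.32. NF-kB target genes fell in 3 of 28 and rose in 1 (adjusted p = 0.26 with an estimated correlation): Bcl3 was at -0.96 ± 0.16, Nfkb1 at -0.59 ± 0.11 and Il1a at 1.08 ± 0.25. Markers of other cell types also differed between the gates by camera, all with adjusted p of 0.19 or more with an estimated correlation. They were monocyte markers (median -0.35, 4 of 18 lower), erythrocyte and platelet genes (0.55), hepatocyte markers (0.46), sinusoidal endothelial markers (0.74) and cDC1 markers (-0.61). Without curcumin DiI-positive replicate 3 the sinusoidal endothelial median was 0.03 (adjusted p = 0.53) and the cDC1 median -1.01. The latter was -0.25 (adjusted p = 0.20) without curcumin DiI-negative replicate 3 and -0.96 without curcumin DiI-negative replicate 2. The monocyte call ended without curcumin DiI-negative replicate 2 (median -0.18, adjusted p = 0.20), and the median was -0.72 without replicate 3 of that gate. The erythrocyte and platelet call ended without curcumin DiI-positive replicate 3 (adjusted p = 0.053) or curcumin DiI-negative replicate 2 (0.051).

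In all, 437 of 14227 genes passed, 200 higher and 237 lower, and 154 by more than 2-fold; the libraries did not overlap for 20.6% of genes, against 10% by chance. The count was 266, 135 and 1088 without curcumin DiI-positive replicate 1, 2 or 3, 114 and 236 without curcumin DiI-negative replicate 1 or 3, and 706 without replicate 3 of both gates. It was 57 with the depth covariate, 248 with no filter and 40 (31 higher and 9 lower) when only the 6 libraries compared were fitted.

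The gate comparisons under the 2 liposomes share no library. They had 97 rises in common, where independent lists would share 2.6, and 125 falls in common, where independent lists would share 3.8; no gene passed in opposite directions. Across genes, which are not independent replicates, the 2 sets of log2 fold changes correlated with r = 0.71. No gene passed the limma test of the difference between them, which is also the test of whether the curcumin effect differed between gates (smallest adjusted p = 0.999; 527 genes at an unadjusted p under 0.05, where 711.35 are expected by chance). That count was 1 without curcumin DiI-positive replicate 1 (Tcaf1), without replicate 2 (Galnt18) or without empty DiI-positive replicate 3 (Fras1). It was 2 without curcumin DiI-positive replicate 3 (Cps1 and Aldh1a1), and 1 without curcumin replicate 3 of both gates (Cps1). These genes were chosen after their values were seen.

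**Figure D2:**
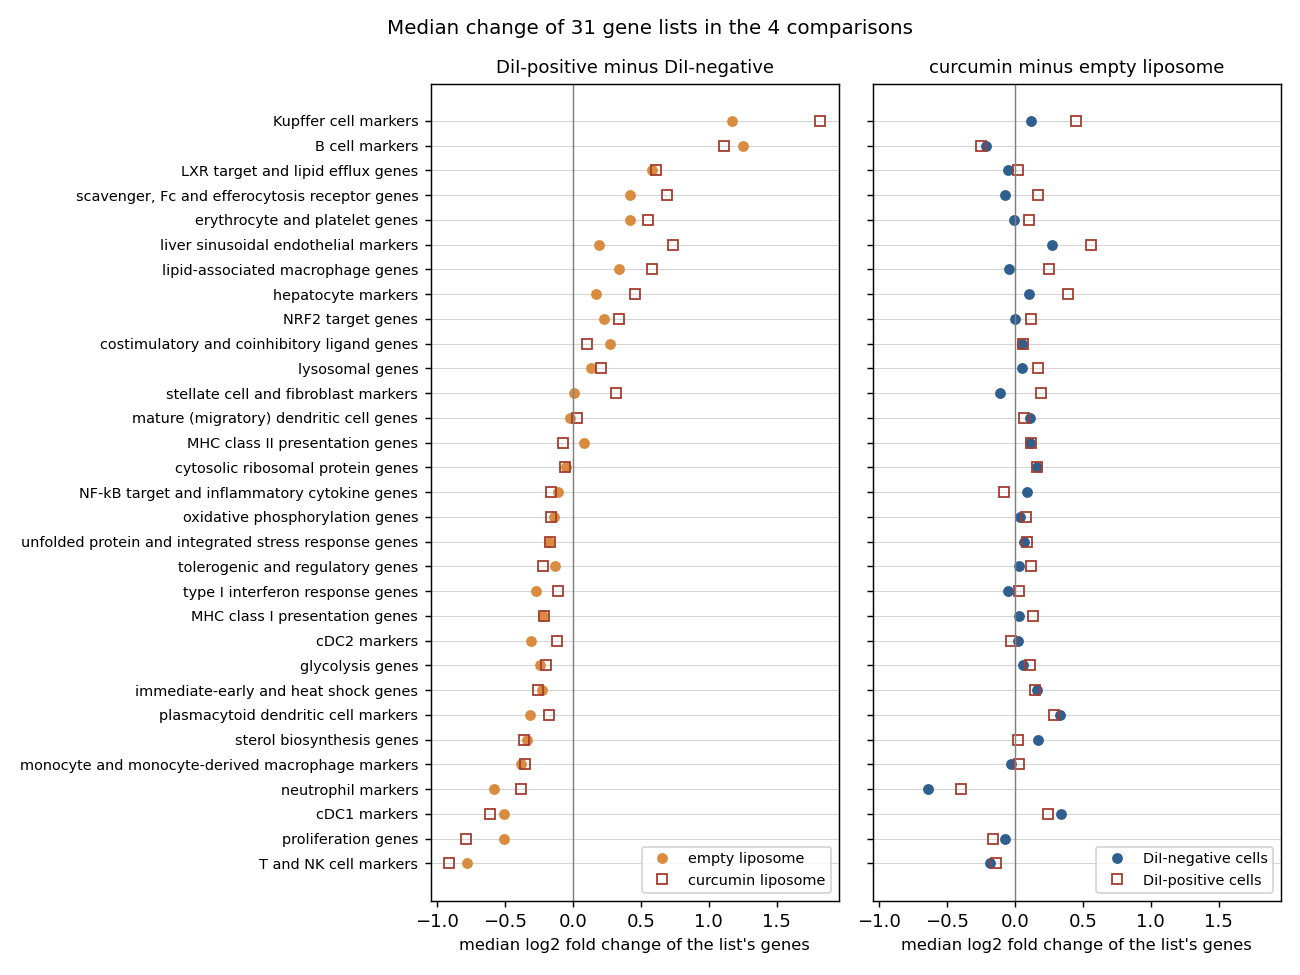
Median log2 fold change (x axis) of the measured genes of each of 31 gene lists (y axis), for DiI-positive minus DiI-negative cells under each liposome (left) and for curcumin minus empty liposome in each gate (right). Kupffer cell markers (1.17 and 1.82) and B cell markers (1.25 and 1.11) have the highest medians on the left, and T and NK cell markers (-0.78 and -0.91) the lowest; medians on the right lie between -0.64 and 0.56.

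The comparison of curcumin with empty liposomes asks what the cargo did to the cells that received it. In DiI-positive cells no gene passed the threshold. The smallest p-values belonged to Aldh1a1, a retinaldehyde dehydrogenase (0.55 ± 0.08, limma adjusted p = 0.30), Pbld2 (0.76 ± 0.13), Sapcd1 (-0.36 ± 0.06), Cass4 (-0.90 ± 0.17) and Ap1g2 (-0.44 ± 0.08), the last 4 with an adjusted p of 0.42. Hmox1, a target of the NRF2 stress response, was at 12.98 ± 0.53 (SD, n = 3) after curcumin and 12.28 ± 0.35 after empty liposomes (0.70 ± 0.29, adjusted p = 0.58). Without curcumin DiI-positive replicate 3 the difference in Hmox1 was 0.39 (adjusted p = 0.64). The inflammatory genes Tnf (-0.06 ± 0.21), Il1b (-0.37 ± 0.25), Il6 (0.00 ± 0.09) and Il12b (0.05 ± 0.17), the cytokine gene Il10 (0.17 ± 0.11) and the NF-kB inhibitor Nfkbia (0.08 ± 0.10) had adjusted p-values of 0.71 to 1.0. Itgax, H2-Ab1 and Cd74 were at 0.26 ± 0.25, 0.11 ± 0.09 and 0.05 ± 0.10. The NF-kB target list had a median of -0.08 and was not called (adjusted p = 0.49), and the NRF2 target list had a median of 0.12 (adjusted p = 0.023, and 0.46 as the adjusted p with an estimated correlation). Hepatocyte markers (median 0.39; 7 of 15 adjusted over the list alone, 0 over all genes), Kupffer cell markers (0.45), sinusoidal endothelial markers (0.56) and neutrophil markers (-0.40) were among the 16 of 31 lists called at the preset correlation. No call held with an estimated correlation (lowest adjusted p = 0.46). Without curcumin DiI-positive replicate 3 the sinusoidal endothelial median was -0.02 (adjusted p = 0.69), the Kupffer cell median 0.22 (0.12), the neutrophil median -0.32 (0.20) and the NRF2 median 0.04 (0.50). The hepatocyte list stayed called without any 1 library, with medians from 0.25 without empty DiI-positive replicate 1 to 0.48 without curcumin DiI-positive replicate 3. The sinusoidal endothelial median was 1.15 without curcumin DiI-positive replicate 1 and 1.00 without replicate 2. Calls also ended without empty DiI-positive replicate 1 (Kupffer cell markers, adjusted p = 0.18), empty DiI-positive replicate 2 (NRF2 targets, 0.24), empty DiI-positive replicate 3 (neutrophil markers, 0.087) and curcumin DiI-positive replicate 2 (neutrophil markers, 0.14).

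Curcumin replicate 3 stood apart in several marker lists. In DiI-positive cells its mean was 10.71 for cDC1 markers, against at most 9.62 in the other 5 libraries, 9.58 for plasmacytoid dendritic cell markers, against at most 8.36, and 9.79 for sinusoidal endothelial markers, against at most 7.68. Its B cell marker mean was 11.81, against at least 12.65 in the other 5. The count of 0 genes stood beside 1165 genes at an unadjusted p under 0.05, where 711.35 are expected by chance. The unadjusted count was 758 with gate weights, 713 with library weights and 694 with only the 6 libraries fitted, all close to the chance number. In the other alternatives with all 12 libraries and the same 14227 genes it stayed above that number, from 1138 (robust prior) to 1386 (depth covariate). Libraries did not overlap for 10% of genes, the share that chance gives. The count was 3 without curcumin DiI-positive replicate 1 (Tcaf1, Itih4, Osmr), 3 without replicate 2 (Mxra8, Galnt18, Cd300lg) and 4 without replicate 3 (Cps1, Pbld2, Serpina1b, Aldh1a1). It was 2 without empty DiI-positive replicate 3 (Fras1, Kcnj16) and 3 without curcumin replicate 3 of both gates (Cps1, Pbld2, Aldh1a1). Genes outside the naming rule were chosen after their values were seen.

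In DiI-negative cells no gene passed either (smallest limma adjusted p = 0.72; 469 genes at an unadjusted p under 0.05, below the 711.35 expected by chance). The unadjusted count was 851 with gate weights, 1000 with library weights and 813 with only the 6 libraries fitted, all above the chance number. In the other alternatives with all 12 libraries and the same 14227 genes it stayed below that number, from 450 (quantile normalization) to 634 (cell marker covariates). The smallest p-values were those of the adhesion molecule Chl1 (-0.81 ± 0.13), Gpr15 (-0.49 ± 0.09, adjusted p = 0.94), the mast cell and basophil protease Prss34 (-1.57 ± 0.29, adjusted p = 0.94), Mrgpra2b (-0.57 ± 0.12) and the integrin Itgb3 (-0.95 ± 0.21). Hmox1 was at 0.48 ± 0.29, Nfkbia at 0.20 ± 0.10, Il1b at -0.46 ± 0.25, Tnf at 0.13 ± 0.21, Il6 at 0.11 ± 0.09, Il12b at -0.05 ± 0.17 and Il10 at 0.03 ± 0.11, each with an adjusted p of 1.0. Camera called 13 of 31 lists in these cells, and no call held with an estimated correlation (lowest adjusted p = 0.37). Among them were the NF-kB target list (median 0.09, 20 of 28 positive, adjusted p = 0.029; 0.49 with an estimated correlation), MHC class II presentation genes (0.11), cDC1 markers (0.34), plasmacytoid markers (0.33) and T and NK cell markers (-0.18). The NF-kB call ended without curcumin DiI-negative replicate 1 (adjusted p = 0.095) or 2 (0.33) or empty DiI-negative replicate 1 (0.35), and the MHC class II call without curcumin DiI-negative replicate 2 (0.063). Without curcumin DiI-negative replicate 3 the cDC1 median was -0.04 (adjusted p = 1.0) and the plasmacytoid median 0.17 (0.43). Neutrophil markers had the lowest list median (-0.64) and cytosolic ribosomal protein genes the smallest camera p (median 0.16, 22 of 22 positive); both calls were lost with an estimated correlation (adjusted p = 0.38 and 0.42). The neutrophil median was -0.30 without curcumin DiI-negative replicate 3, and the ribosomal median 0.10 without curcumin DiI-negative replicate 2. Without the latter library the difference in Hmox1 was 0.20. Curcumin replicate 3 had the highest cDC1 and plasmacytoid marker means of this gate too, 11.23 against at most 10.40 and 9.59 against at most 8.71. Across genes, the curcumin effects of the 2 gates correlated with r = 0.23. Klrb1c, Klrd1, Klrk1 and Cd209a belong to families of similar genes, and how reads shared within such families were counted is not given in the sources used here.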

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

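The list tests named here were planned; the permutation tests were chosen after the results were seen. The camera test of the difference called 2 gene lists whose curcumin effect differed between gates, and both calls were lost with an estimated correlation (adjusted p = 0.91 for both). Kupffer cell markers had a median difference of 0.40 on the log2 scale (adjusted p = 0.032; 18 of 19 genes positive) and lipid-associated macrophage genes one of 0.24 (adjusted p = 0.032; 12 of 14 positive). The direction is that of a larger curcumin effect in DiI-positive cells: the list means differed between curcumin and empty liposome by 0.53 in DiI-positive and 0.12 in DiI-negative cells for Kupffer cell markers, and by 0.19 and -0.04 for lipid-associated macrophage genes.

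Spread of the list means between libraries is a candidate explanation, and the tests leave it standing. When liposome was reassigned within each gate in all 400 ways, differences as large as the real ones were common (two-sided exact permutation p = 0.52 for the Kupffer cell list and 0.29 for the macrophage list). Over the other alternatives run, the adjusted p of camera at the preset correlation ranged from 2.8e-06 to 0.79 for Kupffer cell markers and from 6.8e-05 to 0.53 for the macrophage list. The adjusted p of fry, which tests a list against no change, was 0.93 for both. A curcumin effect on macrophage genes that depends on uptake stays open and untested beyond this.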

How the results depend on the processing

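Alternatives described as added were chosen after seeing the data. Leaving out each library in turn gave 85 to 263 genes for the gate comparison under empty liposome (main count 419) and 114 to 1088 under curcumin liposome (437). It gave 0 to 4 for curcumin in DiI-positive cells (0), 0 in every case for curcumin in DiI-negative cells (0), and 0 to 2 for the difference between gates (0). Fewer libraries leave less information, but why the count rose without curcumin DiI-positive replicate 3 was not tested. For the empty and curcumin gate comparisons, no filter gave 263 and 248 and the added depth covariate 170 and 57. Library weights gave 789 for the former, and fitting only the 6 libraries compared gave 40 for the latter. Without curcumin replicate 3 of both gates the counts were 706 for the curcumin gate comparison, 3 for curcumin in DiI-positive cells and 1 for the difference between gates; these causes were not tested. The remaining alternatives kept each count within 1.5 times of its main value. Replicate numbers were not taken to pair libraries in the main fit. Deviations of same-numbered libraries correlated from 0.0037 to 0.33 in the gate comparisons, all positive, and from -0.11 to 0.17 between curcumin and empty liposome. In the empty gate comparison 6 of 6 libraries matched their own number best, and in the curcumin gate comparison 3 of 6. A pairing of the gates by number can therefore not be excluded. The replicate block gave 405 and 407 genes for the gate comparisons and 0 for the rest, and the replicate block within liposome gave 390, 448 and 0 for the difference. Of 123 named gene results past the threshold, all in the gate comparisons, 20 passed in every alternative run for them and none changed direction. The cell marker covariates were not run for the gate comparisons, so these calls were not adjusted for cell mixture. Of the 123, 83 were lost with the depth covariate, 62 with only the 6 libraries fitted and 34 with no filter. Of 70 list calls, 4 held with an estimated correlation (T and NK cell markers and sterol biosynthesis genes in both gate comparisons) and 20 with fry. In 3 calls of a curcumin effect, on 2 lists, camera's direction turned without curcumin replicate 3. For sinusoidal endothelial markers in DiI-positive cells camera's direction stayed, although their median turned from 0.56 to -0.02. With 1 library left out, the adjusted p of cDC1 markers ranged from 0.0011 to 0.69 in DiI-positive cells and from 1.4e-09 to 1.0 in DiI-negative cells, and that of B cell markers in DiI-positive cells from 3.8e-05 to 0.20. The upper ends came without replicate 3 of the same gate; without replicate 3 of both gates the values in DiI-positive cells were 0.50 for cDC1 and 0.084 for B cell markers. DESeq2, other size factors and voom quality weights could not be run without counts. Depth per library is unknown, so what lies near the floor of the scale, such as Il6 and Il12b, cannot be judged. That limit covers the fall of Il6 in the curcumin gate comparison, although it passed the threshold.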

Other observations

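All tests in this part were chosen after the results were seen, except the counts over other splits of the libraries. Among 121 immunoglobulin V segment genes tested, DiI-positive cells were most enriched in 2 of them. Ighv11-2 had a log2 fold change of 3.76 ± 0.26 under empty liposome (limma adjusted p = 0.00016) and 2.62 ± 0.26 under curcumin liposome (adjusted p = 0.0021). Igkv14-126 had 2.39 ± 0.23 and 1.56 ± 0.23 (adjusted p = 0.0013 and 0.0069). They ranked 1 and 2 of the 121 under both liposomes, whereas the median V segment was at 0.28 and 0.27. The lowest of the 6 DiI-positive libraries (7.85 for Ighv11-2, 7.25 for Igkv14-126) lay above the highest of the 6 DiI-negative libraries (6.00 and 6.26). Many V segments resemble each other closely, and how shared reads were counted is not given in the sources used here.

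A larger share of all B cells would be expected to raise these segments no more than B cell markers, whose mean change was 1.14. The mean of the 2 segments exceeded that by 1.44, more than the 2 highest V segments did in any other of the 924 splits of the 12 libraries (highest other 1.32; one-sided exact permutation p = 0.00108, the smallest these splits can give). The other splits mix or swap the gates, so none holds a general rise of B cells, and this p-value does not test that explanation. In size, both segments rose beyond the range of the B cell markers under empty liposome (0.77 to 1.30). Under curcumin liposome that range reached 1.38. Ighv11-2 exceeded it (2.62 ± 0.26), and Igkv14-126 (1.56 ± 0.23) lay within its standard error of it. The expectation also assumes that the markers come from B cells alone. Of the other V segments, the largest rise was 1.52 ± 0.35 (Igkv3-12) under empty and 1.19 ± 0.21 (Iglv2) under curcumin liposome. Ighv11-2 lay beyond these values and their standard errors under both liposomes, which argues against a general rise as its whole cause. For Igkv14-126 the standard errors under curcumin liposome overlapped, so a general rise as its whole cause stays open. Ighv11-2 and Igkv14-126 are known as partners in receptors of B-1 cells that bind phosphatidylcholine, a common liposome lipid, and a hypothesis is that DiI-positive cells may include such B cells bound to the liposomes. The other V pair described for this specificity, Ighv12-3 and Igkv4-91, gave no decision: it ranked at 88.6% among 10000 random pairs of V segments with similar means, and Ighv12-3 (mean 4.51) lies close to the floor. Ighv12-3 passed under empty liposome (0.46 ± 0.07, adjusted p = 0.0081) but not under curcumin liposome (0.06 ± 0.07, adjusted p = 0.68), and Igkv4-91 in neither (0.55 ± 0.17 and 0.48 ± 0.17, adjusted p = 0.11 and 0.15). The lipids of these liposomes are not given in the sources used here.

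The rise of Kupffer and B cell markers and the fall of T and NK cell markers in DiI-positive cells were weighed against sequencing depth and cell mixture. With the depth index as a covariate the gate effect on the list means went from 1.97 ± 0.26 to 1.75 ± 0.34 (Kupffer), 1.14 ± 0.21 to 1.00 ± 0.27 (B) and -0.86 ± 0.08 to -0.83 ± 0.11 (T and NK). At least 87.3% was kept with wider standard errors, which argues against depth as the whole cause. Cell mixture is consistent with B and Kupffer cell markers moving together from library to library within groups. Their mean correlations of 0.87 and 0.46 exceeded 100% of 10000 random lists of the same size and mean level, which a coordinated change within a cell type would also give. Marker lists hold genes expressed together, so random lists are a weak standard. Curcumin replicate 3 had a low B cell marker mean in DiI-positive (11.81 against 12.88 and 12.90) and DiI-negative cells (11.08 against 11.59 and 11.62). The correlation was not computed without it. Under empty liposome the B cell markers changed by similar amounts (0.77 to 1.30), but the Kupffer cell markers (-0.20 to 4.52) and the T and NK cell markers (-1.81 to -0.07) did not. For T and NK cell markers the correlation of 0.066 exceeded 94% of random lists, which does not decide. The sort on CD11c and MHC class II need not exclude every Kupffer or B cell, and how many of either passed it was not measured. Mouse T and NK cells carry little MHC class II as a rule, so the sort would remove most of them, and how many remained was not measured. All 14 B cell markers rose by similar amounts under empty (0.77 to 1.30) and curcumin liposome (0.69 to 1.38). For these B cell genes, this argues against a change within dendritic cells as the whole cause. It does not separate a larger share of B cells from a change within B cells. For the Kupffer and the T and NK cell lists, whether uptake selects these cells or changes expression within dendritic cells stays open.

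In other splits of the same 6 libraries, the highest count was 0 genes for the empty gate comparison (real count 419, reached by 1 of 10 splits) and 7 for the curcumin gate comparison (real 437, 1 of 10). With 10 splits no share under 0.05 can be had. For the results with a real count of 0, every split reaches that count whatever the data, so splits say nothing about them. This holds for curcumin in DiI-positive cells (10 of 10 splits, highest other 6), in DiI-negative cells (10 of 10, highest other 1) and for the difference between gates (100 of 100 drawn splits, highest other 3). Averaging the curcumin effect over both gates (6 against 6 libraries) also left 0 genes past the threshold, with 1119 at an unadjusted p under 0.05 and a smallest adjusted p of 0.40.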
